A study of Arabidopsis thaliana with 27 samples.

How the data were processed

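The samples were seeds of 3 Arabidopsis thaliana lines (fae1, CL37 and PDAT) at 3 stages after flowering, with 3 biological replicates (A, B and C) per line and stage, 27 libraries in all. Libraries were made with the Illumina TruSeq mRNA v2 kit. The deposited files hold raw counts of reads per gene, 1 file per library, with 33602 genes and 5 summary lines of the counting tool. A further table by the authors holds FPKM (fragments per kilobase and library size), 1 pooled value per line and stage without a spread that was used here. The submitters' processing notes name bcl2fastq 1.8.2, Trimmomatic 0.22, TopHat2 2.0.3, HTSeq 0.5.4p3 and Cufflinks 2.0.1 without roles, and the build TAIR10. They state neither the settings nor how strands were used in counting. The summary lines, 4.68% to 20.5% of each file's total, were kept out of library sizes and tests, except that the percent of non-unique alignments among them served as a covariate in an alternative fit. Gene counts per library ran from 4126510 to 22403287, and replicate pairs within a group differed by more than counting error (chi-square per degree of freedom 2.75 to 236), so the spread between replicates and not depth set the precision of most genes.

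Groups were the 9 combinations of line and stage in the labels, and the comparisons, gene lists, tests and most alternatives were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1): TMM scaling, the edgeR expression filter on the 9 groups, which left 18897 genes, a robust quasi-likelihood fit over all 27 libraries (common biological coefficient of variation 0.209), and 2-sided tests of contrasts. P values were adjusted over all tested genes by Benjamini-Hochberg, and genes at an adjusted p below 0.05 are called. The contrasts were the 3 pairs of lines at each stage and over the mean of stages, 11-12 against 7-8 days in each line, and the change of each line difference between these stages (interaction). Folds are edgeR log2 values with a standard error (SE), and levels are CPM, counts scaled to library size with TMM factors. Principal components used log2 CPM with a prior count of 2. DESeq2 1.42.0 was run as another tool, where 7 to 2571 genes per contrast got no adjusted p.

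The 21 gene lists were written in advance from general knowledge: plastid fatty acid synthesis, sugar supply, triacylglycerol synthesis, oil bodies, storage proteins, LEA proteins, seed regulators, beta-oxidation, endoplasmic reticulum (ER) stress, heat shock, detoxification, jasmonate, photosynthesis, cell division, phospholipid turnover, cutin and suberin, seed coat flavonoids, seed coat mucilage, endosperm, embryo patterning and silique wall. Of 445 members written, 389 matched their locus by symbol and 55 by description in the reference tables, and 1 did not match and was left out. Lists were tested with camera at a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated per list, adjusted over the lists of a contrast. Annotated terms with 10 to 500 tested genes were tested for excess among called genes by a one-sided hypergeometric test. The background was the tested genes that have an annotated term. That test takes genes as independent, so its p values can be too small where the genes of a term vary together. Gene symbols come from the count files' locus identifiers joined to the reference tables, which gave 10995 genes a symbol. Gene length and GC content came from the reference genome for 32827 genes. The reference and the submitters' build both use TAIR10 locus identifiers, and no coordinate of one was used with the other.

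The genes named follow a rule written in advance. For each line contrast over the mean of stages, the 8 largest rises and 8 largest falls were taken among called genes with the same sign at all 3 stages and an average log2 CPM of at least 2, with up to 4 called members of each list, or the 2 most abundant members if none was called. For development in fae1 the same numbers were taken among genes with the same sign in both steps and all 3 lines, and for single stages and interactions 4 each way. The 9 lipid genes FAE1, FAD2, FAD3, WRI1, PDAT1, PDAT2, DGAT1, ROD1 and BCCP2 are given whatever their test. The text describes a part of the genes so chosen, and leaves out most of those with nearly no counts in a group or whose call was lost without 1 library. GSTU19 at 11-12 days, the levels of genes at single stages and the plotted genes were picked for display from the genes so chosen.

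A developmental score, chosen after the principal components were seen, is the mean log2 CPM of 500 genes that rose minus that of 500 that fell in PDAT. The slope of a line difference on the fae1 change with age was tested by exact permutation over the splits of the 6 libraries. The covariance of CL37 and PDAT effects across genes was set against 20 simulations without effects. Recovery was the median PDAT minus CL37 difference at 11-12 days of the genes called higher in CL37 at 9-10 days, so that no library of the call enters the value. The authors' FPKM columns were fitted as non-negative mixes of the libraries over 16152 genes with a mean count of at least 20. Values were not log-transformed, no pseudocount was used, and the highest values of each column were left out of its fit.

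The pipeline was tested on simulated data with 200 changed genes. At 3 against 3 libraries 59% of 2-fold and 96% of 4-fold changes were recovered, over the mean of stages 91% and 100%, and for an interaction 24% and 87%. A list shift of 0.5 came back as 0.53 and a slope of 0.2 as 0.19. Whether replicate letters pair the libraries was checked from correlations of deviations from group means. Every same-letter pair was above 0.1 for PDAT against CL37 at 7-8 days (0.107 to 0.315) and for PDAT against fae1 at 9-10 days (0.132 to 0.263), and not in the other comparisons, while the labels give no shared batch. Alternatives were RLE and upper-quartile scaling, no filter on low counts, DESeq2, only the groups compared, a replicate block, each library left out in turn, other axes, thresholds and list tests. Added after seeing the data were fits without the fae1 A libraries of 7-8 and 9-10 days, fits without the fae1 and CL37 C libraries of 11-12 days, and fits with the score or the percent of alignments that were not unique as a covariate. Where a library is left out, a group with 2 libraries is assumed to vary like the others.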

Results

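Developing seeds of 3 Arabidopsis thaliana lines were compared by RNA sequencing at 3 stages, 7-8, 9-10 and 11-12 days after flowering. The fae1 line lacks the elongase that makes very long chain fatty acids. The CL37 line is fae1 with the castor bean hydroxylase RcFAH12, which makes hydroxy fatty acids, and the PDAT line is CL37 with a castor bean acyltransferase, RcPDAT1a, that moves acyl groups from phospholipid to triacylglycerol. Per the labels, each of the 9 groups has 3 biological replicates (A, B and C), each of seeds taken from frozen siliques of about 50 plants grown under constant light. The deposited values are counts of reads per gene for the 27 libraries and 1 table of the authors' FPKM values with 1 pooled value per group. Reads were aligned by the submitters to TAIR10, and chromosome positions given here are from that annotation. Counts per library in genes ran from 4126510 (CL37, 9-10 days, replicate B) to 22403287 (PDAT, 9-10 days, replicate C), and 19541 to 22650 genes had at least 1 count. The cruciferin gene CRU3 (AT4G28520), for a seed storage protein, took up to 14.1% of a library, and the 20 most abundant genes together took 9.02% to 54.3%. The percent of alignments that were not unique ran from 4.05% to 19.4% and was 16.6% to 19.4% in the 3 PDAT libraries of 7-8 days against 6.28% to 11.4% in fae1 and 10.4% to 15.8% in CL37.

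Stage separated the libraries more than line did. The first principal component held 64.5% of the variance and the second 9.35%, and the first ordered the libraries by stage, except for the fae1 A library of 7-8 days, which lay among those of 9-10 days. A developmental score, the mean log2 CPM (counts scaled to library size) of the 500 genes that rose with the smallest p in PDAT from 7-8 to 11-12 days minus that of the 500 that fell, put 8 of the 9 libraries of 7-8 days between -3.09 and -2.56. The fae1 A library of 7-8 days stood apart at -0.62, between the fae1 libraries B (-1.26) and C (-0.37) of 9-10 days. The fae1 A library of 9-10 days was lower than those, at -1.54. At 11-12 days the fae1 libraries lay at 1.52, 1.53 and 2.06, below the CL37 libraries (3.11 to 3.60) and the PDAT libraries (2.22 to 3.30). Both fae1 A libraries were kept under their labels, and counts are also given without them. In the authors' FPKM table the pooled columns of fae1 and CL37 at 11-12 days did not match the counts of their own 3 libraries: fitted as a mix of libraries over 16152 genes, 26.77% of the fae1 column and 29.89% of the CL37 column fell on libraries of other lines at the same stage. All values below are therefore from the counts, and counts are also given without the C libraries of these 2 groups.

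**Figure D1:**
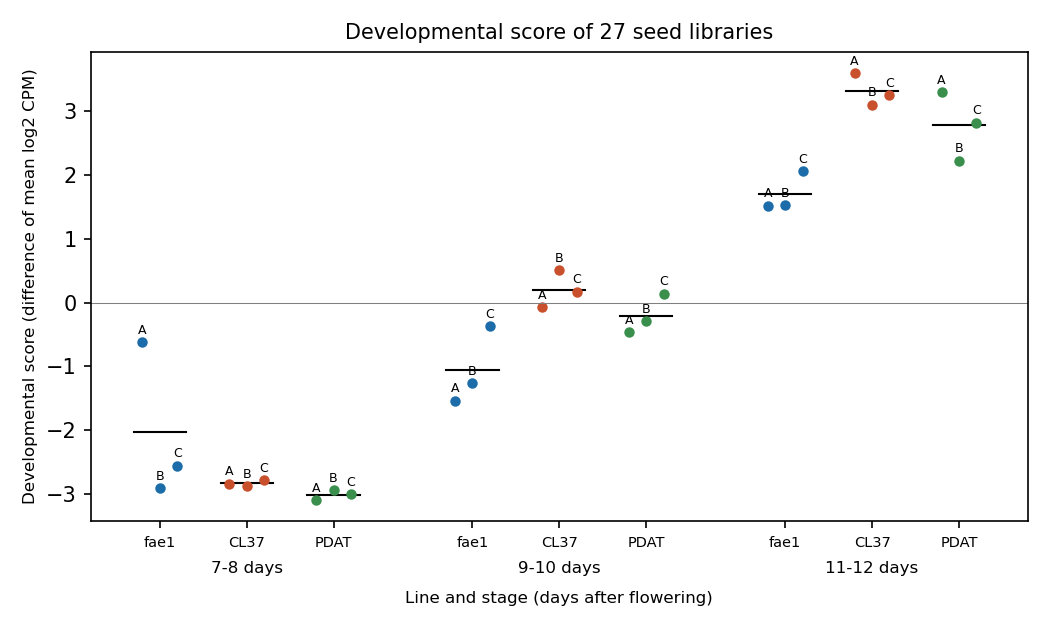
Developmental score of each of the 27 libraries (points, labelled by replicate) by line and stage, with the group mean as a bar; the score is a difference of mean log2 CPM. The fae1 A library of 7-8 days, at -0.62, lies with the libraries of 9-10 days.

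The seed lipid genes chosen in advance were expressed at every stage in all 3 lines. FAE1 itself (AT4G34520, chromosome 4, 16494205 to 16495842, plus strand), the elongase gene that is mutated in all 3 lines, gave 464 ± 308, 711 ± 154 and 1088 ± 35.6 CPM (mean ± SD, n = 3) in fae1 at the 3 stages. At 11-12 days it gave 748 ± 141 in CL37 and 755 ± 73.4 in PDAT. FAD2, the oleate desaturase gene of the endoplasmic reticulum, reached 4424 ± 150 CPM in fae1, 5245 ± 116 in CL37 and 6245 ± 999 in PDAT at 11-12 days. FAD3, for the desaturase that makes linolenate, reached 2871 ± 145, 2705 ± 276 and 3326 ± 440 CPM at that stage. Its value of 694 ± 732 in fae1 at 7-8 days held the A library that stood apart. The oil regulator WRI1 gave 227 ± 30.9 CPM in fae1, 166 ± 21.9 in CL37 and 181 ± 27.9 in PDAT at 11-12 days. ROD1, whose product feeds phosphatidylcholine with diacylglycerol, gave 189 ± 18.3, 193 ± 16.6 and 240 ± 32.8 CPM. CAC1-B (BCCP2), a biotin carrier subunit of plastid acetyl-CoA carboxylase, gave 441 ± 40.2, 276 ± 66.0 and 316 ± 67.4 CPM. The triacylglycerol synthesis gene ATDGAT (DGAT1) gave 110.8 ± 16.0, 125.1 ± 16.0 and 101.9 ± 1.79 CPM. The plant's own acyltransferase gene ATPDAT (PDAT1) was low throughout, at 9.13 ± 0.120 CPM in fae1 at 11-12 days, and its relative AT3G44830 (PDAT2) gave 28.7 ± 7.40 CPM there. In PDAT against CL37 none of these 9 genes passed the test in edgeR at any stage (1, 1 and 0 at unadjusted p below 0.05) or in the change with age (1 at unadjusted p below 0.05), and DESeq2 called 0 at each stage and 1 in the change with age.

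In fae1 seeds, most storage protein, oil body, desiccation (LEA) and cutin genes of the lists rose between 7-8 and 11-12 days. The cell division genes and most photosynthesis and seed coat mucilage genes fell, as did the embryo regulators LEC1 and LEC2. These 7 lists passed camera at the preset correlation, and none passed with an estimated correlation. FAD3 rose in CL37 and PDAT too, by 2.91 and 3.38.

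From 7-8 to 11-12 days, 4528 genes rose and 5012 fell in fae1 in edgeR (9540 of 18897 tested at adjusted p below 0.05), 5575 rose and 5404 fell in CL37 (10979), and 5133 rose and 5048 fell in PDAT (10181). Without the fae1 A libraries of 7-8 and 9-10 days, the fae1 count was 5783 up and 5945 down, and without the fae1 B library of 7-8 days it was 6207 in all. Without the C libraries of fae1 and CL37 at 11-12 days the fae1 count was 7915. All fae1 folds of development below include the A library of 7-8 days, whose storage and desiccation transcripts lay with those of 9-10 days. Of 13 storage protein genes 11 rose (13 when adjusted over the list alone; camera adjusted p = 3.25e-05, and adjusted p = 0.428 with an estimated correlation). Among them were the cruciferin genes CRU1 (log2 fold change 2.21 ± 0.64 SE, adjusted p = 0.00733) and CRU3 (2.21 ± 0.72, adjusted p = 0.015, lost without fae1 C of 7-8 days at adjusted p = 0.0696). The 2S albumin gene SESA1 rose by 2.22 ± 0.66 (adjusted p = 0.00858). Without fae1 A of 7-8 days these 3 rose by 4.56, 5.0 and 4.50. CRU3 went from 36050 ± 53440 CPM to 167000 ± 41860 CPM. Of 18 oil body genes 14 rose and none fell (15 and 1 when adjusted over the list alone; camera adjusted p = 7.18e-05, and adjusted p = 0.428 with an estimated correlation). The oleosin gene OLE3 rose by 2.06 ± 0.48 (adjusted p = 0.00172) and the caleosin gene ATS1 by 2.07 ± 0.50 (adjusted p = 0.00209), or by 3.52 and 3.61 without fae1 A of 7-8 days. Of 20 genes for late embryogenesis abundant (LEA) proteins, which protect drying cells, 16 rose (camera adjusted p = 3.25e-05, and adjusted p = 0.428 with an estimated correlation). The dehydrin gene RAB18 rose by 3.59 ± 1.06 (adjusted p = 0.00852). RAB18 was at 5.69 without fae1 A of 7-8 days and at 1.23 (adjusted p = 0.288) without fae1 A of 11-12 days. Of 15 cutin and suberin genes 14 rose (camera adjusted p = 7.18e-05, and adjusted p = 0.386 with an estimated correlation). Of 24 genes of fatty acid beta-oxidation and the glyoxylate cycle 14 rose and 2 fell (15 and 2 when adjusted over the list alone; camera adjusted p = 0.00348, and adjusted p = 0.428 with an estimated correlation). The isocitrate lyase gene ICL rose by 2.08 ± 0.53 (adjusted p = 0.0033; 3.66 without fae1 A of 7-8 days). Some counts rest on single libraries. Of the storage protein genes 4 were called without fae1 C of 7-8 days, of the LEA genes 9 without fae1 A of 11-12 days, and of the beta-oxidation genes 8, 10 and 9 without fae1 B or C of 7-8 days or fae1 A of 11-12 days. ATRALF1, for a small secreted peptide, had one of the largest rises, 4.52 ± 0.58 (adjusted p = 6.01e-06).

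All 26 cell division genes fell (camera adjusted p = 6.06e-23, and adjusted p = 0.365 with an estimated correlation). They include PCNA1, for a sliding clamp of DNA replication (-3.81 ± 0.52, adjusted p = 1.17e-05), the kinase gene AtAUR1 (-3.72 ± 0.42, adjusted p = 1.66e-06) and SYP111, for the syntaxin of the cell plate (-3.39 ± 0.33, adjusted p = 6.87e-07). Of 44 photosynthesis genes 41 fell (camera adjusted p = 8.94e-18, and adjusted p = 0.386 with an estimated correlation). The light-harvesting gene LHCB2 was at -2.90 ± 0.30 (adjusted p = 7.73e-07) and the photosystem II gene PSBQA at -2.47 ± 0.23 (adjusted p = 5e-07). Of 14 seed coat mucilage genes 12 fell and 1 rose (camera adjusted p = 7.18e-05, and adjusted p = 0.428 with an estimated correlation). The galactosidase gene MUM2 fell by 3.46 ± 0.43 (adjusted p = 4.54e-06). Of 14 flavonoid genes 8 fell and 1 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0511). The proanthocyanidin genes TDS4 and BAN fell by 3.29 ± 0.54 (adjusted p = 7.67e-05) and 2.79 ± 0.54 (adjusted p = 0.000383). Of 10 endosperm genes 6 fell and 1 rose (camera adjusted p = 0.0394, and adjusted p = 0.428 with an estimated correlation). The regulator RGE1 fell by 3.11 ± 0.42. Among 19 seed regulators 5 rose and 7 fell (6 and 7 when adjusted over the list alone), and the embryo regulators LEC1 (-3.41 ± 0.56, adjusted p = 7.81e-05) and LEC2 (-3.25 ± 0.56, adjusted p = 0.000104) were among those that fell. Of 39 plastid fatty acid synthesis genes 5 rose and 16 fell (camera adjusted p = 0.108), the acyl carrier protein gene ACP4 by 2.35 ± 0.31 (adjusted p = 9.33e-06). Among the desaturases FAD3 rose by 2.05 ± 0.45 (adjusted p = 0.000962) and FAD2 by 0.78 ± 0.21 (adjusted p = 0.00518), and FAE1 rose by 1.23 ± 0.30 (adjusted p = 0.00202). The FAD2 call ended with the percent of non-unique alignments as a covariate (0.60 ± 0.23, adjusted p = 0.0516). Of 29 triacylglycerol synthesis genes 11 rose and 5 fell, with PDAT2 up by 1.58 ± 0.40 (adjusted p = 0.00277), while WRI1 (0.05) and PDAT1 (-0.06) did not pass the test. Without fae1 A of 7-8 days FAD3 rose by 3.40, FAE1 by 1.92 and PDAT2 by 2.77. In the same fae1 contrast, 5 rose and 1 fell of 12 sugar supply genes, 7 and 3 of 28 endoplasmic reticulum (ER) stress genes, 5 and 2 of 11 heat shock genes, 8 and 3 of 21 detoxification genes, and 5 and 4 of 17 jasmonate genes. The last 3 lists gave 7 up and 2 down of 11 phospholipid turnover genes, 1 and 2 of 11 embryo patterning genes, and 2 and 5 of 12 silique wall genes. Without fae1 B or C of 7-8 days the genes called fell to 3 and 3 (sugar supply), 9 and 9 (triacylglycerol synthesis), 3 and 3 (heat shock), 4 and 5 (jasmonate), 4 and 3 (phospholipid turnover), 1 and 1 (embryo patterning) and 3 and 3 (silique wall). Without fae1 B of that stage 13 plastid fatty acid synthesis and 4 endosperm genes were called, and 6 seed regulators without fae1 C. Leaving out fae1 A of 11-12 days gave 3 heat shock, 1 embryo patterning and 3 silique wall genes, leaving out fae1 C of that stage gave 4 endosperm and 3 silique wall genes, and leaving out fae1 A of 7-8 days gave 6 embryo patterning genes.

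In CL37 seeds, detoxification genes and some endoplasmic reticulum stress and jasmonate genes stood above fae1. Of these 3 lists only detoxification also passed camera with an estimated correlation. A methionine breakdown gene, ATMGL, stood below fae1 at all 3 stages. Some genes of fatty acid synthesis and photosynthesis were lower in CL37 at 11-12 days.

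The number of genes that differed between CL37 and fae1 grew with age. At 7-8 days 1 gene was higher and 4 were lower in edgeR (1426 at unadjusted p below 0.05), and DESeq2 called 114. With RLE or upper-quartile factors 4 were lower and none higher there (1400 and 1413 at unadjusted p below 0.05). At 9-10 days 133 were higher and 7 lower, and at 11-12 days 1990 were higher and 952 lower. Of these, 1105 and 162 differed by at least 2-fold at 11-12 days (104 and 6 at 9-10 days). Over the mean of stages 1060 were higher and 278 lower. Without the fae1 A libraries of 7-8 and 9-10 days the counts were 4 up and 4 down, 92 and 4, 2593 and 1880, and 1259 and 426 for the 3 stages and their mean. Without the C libraries of fae1 and CL37 at 11-12 days they were 3, 120, 1940 (1476 up and 464 down) and 1090 in all. At 7-8 days the total was 8 without fae1 A, 161 without fae1 B, 67 without fae1 C, 3 without CL37 A, 2 without CL37 B and 3 without CL37 C. At 9-10 days it was 42 without fae1 A, 82 without fae1 B, 83 without CL37 A and 61 without CL37 B. At 11-12 days it was 1659 without CL37 A, and for the mean of stages 2088 without the fae1 A library of 7-8 days. Scaling changed the split at 11-12 days, which was 1810 up and 1491 down with upper-quartile factors.

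WRKY33, for a transcription factor of defence, was near the detection limit in fae1 and reached 47.6 ± 8.27 CPM in CL37 at 11-12 days against 0.589 ± 0.341 in fae1. PMZ, for a stress-associated zinc finger protein, gave 128 ± 39.8 CPM in CL37 and 0.671 ± 0.347 in fae1 at that stage (log2 fold change 7.58 ± 0.77, adjusted p = 2.47e-07) and was higher by 3.96 ± 0.51 over the mean of stages (adjusted p = 1.6e-05). The trihelix factor gene AT5G01380 was higher by 3.90 ± 0.29 (adjusted p = 4.97e-09) and the GRAM domain gene AT5G13200 by 3.51 ± 0.35 (adjusted p = 4.72e-07). Of 21 detoxification genes 8 were higher and none lower over the mean of stages (11 when adjusted over the list alone; camera adjusted p = 7.75e-11, and adjusted p = 0.00678 with an estimated correlation). The count was 5 without CL37 A of 7-8 days. The called members included the cytochrome P450 gene CYP81D8 (3.16 ± 0.33, adjusted p = 9.47e-07). ATGSTU22, a tau class glutathione transferase gene that is not in the list, was higher by 3.80 ± 0.48 (adjusted p = 1.01e-05). At 11-12 days 15 of the 21 were higher (15 and 1 lower when adjusted over the list alone; camera adjusted p = 2.54e-18, and adjusted p = 0.000158 with an estimated correlation). GSTU19 gave 1166 ± 128.7 CPM in CL37 and 231 ± 7.95 in fae1 at that stage, ATGSTU22 81.7 ± 22.1 and 0.481 ± 0.229, and CYP81D8 86.5 ± 26.8 and 0.858 ± 0.275.

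Of 28 ER stress genes 8 were higher over the mean of stages (12 when adjusted over the list alone; camera adjusted p = 1.12e-09, and adjusted p = 0.146 with an estimated correlation). BZIP60, a transcription factor gene of the unfolded protein response, was higher by 0.88 ± 0.12 (adjusted p = 1.47e-05) and gave 241.7 ± 54.6 CPM in CL37 and 49.9 ± 2.89 in fae1 at 11-12 days. Its target anac103 was higher by 2.51 ± 0.37 (adjusted p = 6.67e-05) and the chaperone partner gene ATERDJ3A by 1.29 ± 0.11 (adjusted p = 5.91e-08). At 11-12 days 11 ER stress genes were higher (13 when adjusted over the list alone; camera adjusted p = 7.36e-06, and adjusted p = 0.346 with an estimated correlation). Of 11 heat shock genes 3 were higher over the mean of stages (7 when adjusted over the list alone; camera adjusted p = 0.000161, and adjusted p = 0.146 with an estimated correlation). The regulator AT-HSFA3 was higher by 1.99 ± 0.37 (adjusted p = 0.00086). Of 17 jasmonate genes 4 were higher (4 when adjusted over the list alone; camera adjusted p = 0.00355, and adjusted p = 0.146 with an estimated correlation). These were the regulator RD22BP1, known as MYC2 (1.41 ± 0.17, adjusted p = 3.85e-06), the repressor genes TIFY9, known as JAZ10 (0.95 ± 0.13, adjusted p = 2.49e-05), and JAZ1 (0.48 ± 0.13, adjusted p = 0.0215), and the biosynthetic gene AOC3 (0.94 ± 0.23, adjusted p = 0.0136). Of 24 beta-oxidation genes 4 were higher (4 when adjusted over the list alone; camera adjusted p = 0.000617, and adjusted p = 0.443 with an estimated correlation). They included the oil body lipase gene SDP1 (0.59 ± 0.13, adjusted p = 0.0064) and the acyl-CoA oxidase gene ACX2 (0.57 ± 0.10, adjusted p = 0.000612). The acyltransferase gene LPAT4, of the triacylglycerol list, was higher by 0.58 ± 0.10 (adjusted p = 0.000635). Among 11 phospholipid turnover genes 2 were higher, PLDALPHA1 among them (0.35 ± 0.09, adjusted p = 0.015), and at 11-12 days 3 were (3 when adjusted over the list alone; camera adjusted p = 0.53). Of 18 oil body genes 1 was higher, AT3G05500, for a lipid droplet protein (0.50 ± 0.09, adjusted p = 0.00061), which gave 1195 ± 196.7 CPM in CL37 and 491 ± 26.2 in fae1 at 11-12 days. Of 15 cutin genes 2 were higher and 1 lower (4 and 1 when adjusted over the list alone; camera adjusted p = 0.00496, and adjusted p = 0.443 with an estimated correlation). The hydroxylase gene CYP86A2 was up by 0.70 ± 0.08 (adjusted p = 3.33e-06) and CYP77A6 was down by 1.16 ± 0.28 (adjusted p = 0.0114, or 0.0803 without the fae1 A libraries). Over the mean of stages, leaving out fae1 A of 7-8 days gave 13 ER stress, 11 beta-oxidation and 3 oil body genes. Of the heat shock genes 1 was called without fae1 A of 9-10 days, CL37 C of 7-8 days, CL37 B or C of 9-10 days, or CL37 A or B of 11-12 days. Of the phospholipid turnover genes 1 was called without fae1 B or C of 9-10 days, fae1 A or B of 11-12 days, any CL37 library of 7-8 or 9-10 days, or CL37 A of 11-12 days. At 11-12 days 7 ER stress genes were called without fae1 B or C, and 1 phospholipid turnover gene without fae1 B. The wax regulator MYBCOV1, known as MYB96, was higher by 1.08 ± 0.20 (adjusted p = 0.00107).

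ATMGL (AT1G64660, chromosome 1, 24028918 to 24030780, plus strand), for the enzyme that breaks down methionine, was lower in CL37 by 2.25 ± 0.28 at 7-8 days (adjusted p = 0.000476), by 1.88 at 9-10 days (adjusted p = 0.00131) and by 2.69 ± 0.29 at 11-12 days (adjusted p = 3.09e-07). Every fae1 library held at least 263 CPM of it and every CL37 or PDAT library at most 130 CPM. SCPL8, for the enzyme that makes the sunscreen ester sinapoylmalate, was lower by 1.7 ± 0.41 over the mean of stages (adjusted p = 0.0114; 0.74 without fae1 A of 7-8 days) and gave 23.0 ± 2.22 CPM in CL37 and 71.6 ± 14.3 in fae1 at 11-12 days. Of 14 flavonoid genes 3 were lower over the mean of stages (8 when adjusted over the list alone; camera adjusted p = 0.000161, and adjusted p = 0.146 with an estimated correlation). The chalcone isomerase gene TT5 was at -0.67 ± 0.11 (adjusted p = 0.000369). The count was 7 without fae1 A of 7-8 days, 5 without fae1 B of 9-10 days and 5 without CL37 A of 7-8 days. TDS4 was lower by 1.35 ± 0.35 (adjusted p = 0.018), lost without the B library of fae1 (adjusted p = 0.0656) or of CL37 (0.0604) at 11-12 days. At 11-12 days 11 of 39 plastid fatty acid synthesis genes were lower and 1 higher (19 and 2 when adjusted over the list alone; camera adjusted p = 3.69e-05, and adjusted p = 0.385 with an estimated correlation). The 12 calls fell to 6, 3 and 6 without fae1 A, B and C of that stage and to 1 without CL37 A. CAC1-B was lower by 0.68 ± 0.19 there (adjusted p = 0.0171), a call lost without fae1 B, fae1 C, CL37 A or CL37 C of that stage (adjusted p of 0.069, 0.05, 0.135 and 0.056). Photosynthesis genes were lower at 11-12 days in 11 of 44 cases (27 when adjusted over the list alone; camera adjusted p = 5.86e-09, and adjusted p = 0.385 with an estimated correlation), or 7, 7 and 5 without fae1 A, fae1 B or CL37 A of that stage. FAE1 (-0.54 ± 0.29, adjusted p = 0.219), WRI1 (-0.45 ± 0.16, adjusted p = 0.054), FAD2 (0.25, adjusted p = 0.462), FAD3 (-0.09), ATDGAT (0.18) and ROD1 (0.03) did not pass at 11-12 days. Most of the called genes, 77.9% of 2942, differed in the direction in which the same gene changed with age in PDAT, against 62.5% of all genes tested, and 1862 of them stayed called with the developmental score as a covariate, a fit that called 2179 up and 2160 down.

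Other lists at 11-12 days in CL37 against fae1 follow. Of 12 sugar supply genes 3 were lower (3 when adjusted over the list alone; camera adjusted p = 0.0188, and adjusted p = 0.416 with an estimated correlation). Of 20 LEA genes 5 were higher (7 when adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.656 with an estimated correlation). Heat shock genes were higher in 5 of 11 cases (8 when adjusted over the list alone; camera adjusted p = 0.0035, and adjusted p = 0.346 with an estimated correlation). Embryo patterning genes were lower in 3 of 11 cases (4 when adjusted over the list alone; camera adjusted p = 0.0333, and adjusted p = 0.346 with an estimated correlation). Silique wall genes were lower in 3 of 12 cases (4 when adjusted over the list alone; camera adjusted p = 0.0091, and adjusted p = 0.346 with an estimated correlation). Of 14 flavonoid genes 4 were lower (5 when adjusted over the list alone; camera adjusted p = 0.000778, and adjusted p = 0.346 with an estimated correlation). None of 13 storage protein genes (camera adjusted p = 0.356) and none of 26 cell division genes (camera adjusted p = 0.323) passed in edgeR, neither over all genes nor over the list alone. At unadjusted p below 0.05 in edgeR they were 0 and 1, and DESeq2 called 0 in both lists. Triacylglycerol synthesis genes (2 of 29 higher, camera adjusted p = 0.68), endosperm genes (1 of 10 higher, camera adjusted p = 0.376) and mucilage genes (1 of 14 lower, camera adjusted p = 0.218) gave the same counts when adjusted over the list alone. Seed regulators had 1 of 19 higher and 1 lower (1 and 5 when adjusted over the list alone; camera adjusted p = 0.268). With 1 library of 11-12 days left out, many of these counts moved. Leaving out fae1 A gave 1 sugar supply, 10 LEA, 3 heat shock, 1 embryo patterning, 2 flavonoid and 1 seed regulator genes. Leaving out fae1 B gave 1 sugar supply, 1 LEA, 3 heat shock, 2 flavonoid and 1 triacylglycerol synthesis genes. Leaving out fae1 C gave 1 sugar supply, 3 LEA and 1 embryo patterning genes. Leaving out CL37 A gave 1 sugar supply, 3 LEA, 1 embryo patterning, 1 silique wall and 1 seed regulator genes, and lost the mucilage call. Leaving out CL37 B gave 6 embryo patterning genes and 4 seed regulators, and leaving out CL37 C gave 1 seed regulator. Annotated terms among the higher genes at this stage included response to chitin (18 of 40 genes, 4.31 expected, adjusted p = 4.63e-06), ubiquitin-dependent protein catabolism (35 of 122, 13.2 expected, adjusted p = 4.63e-06) and response to heat (17 of 52, adjusted p = 0.000871).

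**Figure D2:**
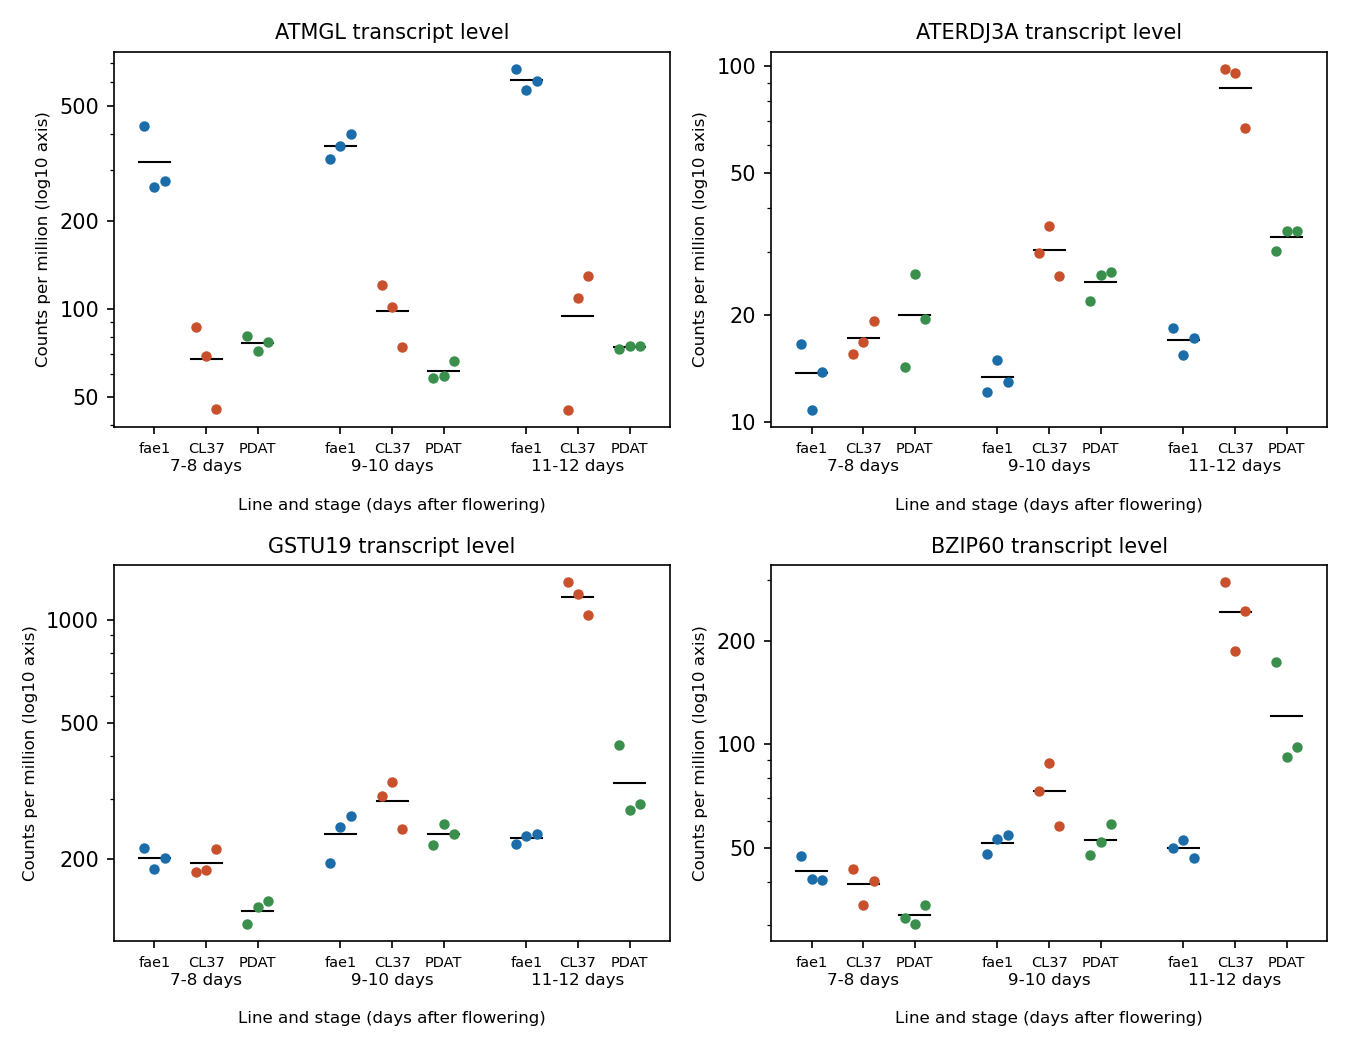
CPM (log10 axis) of 4 genes in each of the 27 libraries by line and stage, with bars at the group means. ATMGL lies at 263 CPM or more in every fae1 library and at 130 or less in every other, while ATERDJ3A, GSTU19 and BZIP60 are highest in CL37 at 11-12 days.

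The change of the CL37 difference with age was tested as an interaction, from 7-8 to 11-12 days. It was positive for 1042 genes and negative for 197 in edgeR (912 and 323 with upper-quartile factors). Of 100 splits of the same libraries 11 gave as many genes, the highest other 1524, so chance was not excluded. On the compared groups only, the total was 587. For 12 of 21 detoxification genes it was positive and for none negative (14 and 1 when adjusted over the list alone; camera adjusted p = 6.77e-15, and adjusted p = 0.000366 with an estimated correlation). LEA genes had 8 of 20 positive (11 when adjusted over the list alone; camera adjusted p = 3.54e-06, and adjusted p = 0.345 with an estimated correlation). The LEA count was 1 without fae1 A of 7-8 days, fae1 B or C of 11-12 days, CL37 A or B of 7-8 days, or CL37 A of 11-12 days, 3 without CL37 C of 7-8 days and 4 without CL37 B of 11-12 days. The largest falls included EMS1, a receptor kinase gene (-1.98 ± 0.43, adjusted p = 0.00592). Without the fae1 A libraries the split was 1697 positive and 1573 negative, and without the C libraries of fae1 and CL37 at 11-12 days the total was 931. The total was 3045 without fae1 A of 7-8 days, 823 without fae1 B of 11-12 days, 807 without CL37 C of 7-8 days and 692 without CL37 A of 11-12 days. The relation of PDAT to fae1 changed with age for 894 genes upward and 550 downward (5320 without the fae1 A libraries, 675 without the C libraries). Totals ran from 354 to 5025 when 1 library was left out, each of the 12 libraries of the contrast moving it by more than 1.5-fold. In that contrast ROD1 rose by 0.89 ± 0.22 relative to fae1 (adjusted p = 0.0206), lost without fae1 A of 11-12 days, PDAT A of 7-8 days or PDAT C of 11-12 days (adjusted p of 0.0616, 0.0565 and 0.0614).

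In PDAT seeds, most of the genes that differed from CL37 were lower. Some detoxification genes, ER stress genes and a lipid droplet gene that stood higher in CL37 than in fae1 were among them. Over the mean of stages, the calls of the ER stress and lipid droplet genes ended with the percent of non-unique alignments as a covariate. Their folds became smaller there and kept their direction.

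PDAT and CL37 differed mainly at 11-12 days, where 18 genes were higher and 482 lower in PDAT in edgeR, 11 and 318 of them by at least 2-fold. At 7-8 days 2 were higher and none lower (2148 at unadjusted p below 0.05), and DESeq2 called 44 and 41. With the replicate block the count at 7-8 days was 6. Deviations of same-letter libraries of the 2 lines from their group means correlated at 0.107 to 0.315 there. Those of CL37 and fae1 at that stage ran from -0.371 to -0.0302, so a pairing by letter was not established. At 9-10 days none was higher and 4 were lower (725 at unadjusted p below 0.05), where DESeq2 called 26 in all. Over the mean of stages 12 were higher and 142 lower, 5 and 68 of them by at least 2-fold. With the percent of non-unique alignments as a covariate these 154 calls fell to 59 (5 up and 54 down), while the median absolute log2 fold change of the 154 went from 0.90 to 0.84 and their median SE from 0.17 to 0.18. The interaction with age was positive for 5 genes and negative for 128. Without the fae1 A libraries, which enter through the shared variance only, the counts were 26 up and 11 down, 0 and 5, 86 and 679, 36 and 254, and 82 and 299 for the interaction. Without the C libraries of fae1 and CL37 at 11-12 days they were 0 (1981 at unadjusted p below 0.05) and 4 in all at 7-8 and 9-10 days, 17 up and 460 down at 11-12 days, and 149 in all for the interaction. At 7-8 days the total was 1 without CL37 B and 0 without CL37 C, PDAT A or PDAT B (1665, 1463 and 1782 at unadjusted p below 0.05). At 9-10 days it was 39 without CL37 C and 0 without CL37 A, PDAT A or PDAT C (680, 643 and 903 at unadjusted p below 0.05). At 11-12 days it was 278 without CL37 A, 311 without PDAT B and 291 without PDAT C. For the mean of stages it was 84 without CL37 A and 96 without CL37 B of 7-8 days, 85 without PDAT A and 100 without PDAT C of that stage. It was 83 without CL37 A, 86 without CL37 B and 94 without PDAT C of 9-10 days, and 88 without CL37 A, 95 without PDAT B and 96 without PDAT C of 11-12 days. For the interaction it was 81 without CL37 C of 7-8 days, 76 and 88 without CL37 A or B of 11-12 days, 74 without PDAT B of 7-8 days and 68 without PDAT C of 11-12 days.

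WRKY33 was lower in PDAT by 2.35 ± 0.33 over the mean of stages (adjusted p = 0.000534) and gave 2.45 ± 0.463 CPM at 11-12 days against 47.6 ± 8.27 in CL37. The zinc finger gene AT3G46080 was lower by 2.54 ± 0.33 (adjusted p = 0.000222) and the senescence gene SAG21 by 1.78 ± 0.27 (adjusted p = 0.00144), from 44.3 ± 20.1 CPM in CL37 to 4.04 ± 2.08 at 11-12 days. PMAT1, for an enzyme that adds malonyl groups to phenolic glucosides, was lower by 1.67 ± 0.25 (adjusted p = 0.000861). AT3G22910, for a calcium pump, was lower by 3.91 ± 0.42 at 11-12 days (adjusted p = 6.35e-06), where it gave 8.86 ± 2.52 CPM against 132 ± 30.9 in CL37 and 3.22 ± 0.380 in fae1. At 9-10 days the poly(ADP-ribose) glycohydrolase gene PARG2 was among the 4 genes lower in PDAT (-2.76, adjusted p = 0.00465), a call lost without CL37 A, PDAT A or PDAT C of that stage (adjusted p of 0.099, 0.0608 and 0.0684). Of 21 detoxification genes 4 were lower over the mean of stages (9 when adjusted over the list alone; camera adjusted p = 4.09e-14, and adjusted p = 0.00126 with an estimated correlation). These were GSTU19 (-0.86 ± 0.09, adjusted p = 5.86e-05), the glutathione transferase gene ATGSTF5_AT2G47730, known as GSTF8 (-1.36 ± 0.16, adjusted p = 8.02e-05), CYP81D8 (-1.87 ± 0.29, adjusted p = 0.00191) and ATGSTU25 (-2.31 ± 0.43, adjusted p = 0.00804, lost without CL37 A of 7-8 days at adjusted p = 0.0807). At 11-12 days 13 of the 21 were lower (14 when adjusted over the list alone; camera adjusted p = 1.26e-27, and adjusted p = 1.01e-05 with an estimated correlation), and GSTU19 gave 333 ± 84.6 CPM against 1166 ± 128.7 in CL37.

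Of 28 ER stress genes 3 were lower in PDAT over the mean of stages (3 when adjusted over the list alone; camera adjusted p = 8.17e-07, and adjusted p = 0.382 with an estimated correlation), with BZIP60 at -0.59 ± 0.12 (adjusted p = 0.0114). The value of anac103 was -1.75 ± 0.34 (adjusted p = 0.0108), lost without CL37 A of 9-10 days at adjusted p = 0.0519. The third, ATERDJ3A (-0.49 ± 0.11, adjusted p = 0.0315), was lost without CL37 B or C of 7-8 days, CL37 A or B of 9-10 or 11-12 days, PDAT A or C of 7-8 days, PDAT A, B or C of 9-10 days, or PDAT B or C of 11-12 days (adjusted p of 0.0516 to 0.0875). All 3 calls ended with the percent of non-unique alignments as a covariate (BZIP60 at -0.51 ± 0.12, adjusted p = 0.0756, anac103 at -1.64 ± 0.37, adjusted p = 0.0592, and ATERDJ3A at -0.41 ± 0.12, adjusted p = 0.204), and without CL37 A of 9-10 days the list had 1 call. At 11-12 days 4 ER stress genes were lower (9 when adjusted over the list alone; camera adjusted p = 1.47e-08, and adjusted p = 0.378 with an estimated correlation), and BZIP60 gave 121.1 ± 45.3 CPM in PDAT. The lipid droplet gene AT3G05500 was lower by 0.43 ± 0.09 (adjusted p = 0.0179), lost without CL37 A of 11-12 days (adjusted p = 0.0503) or PDAT A of 7-8 days (0.0501), and with that covariate (-0.34 ± 0.09, adjusted p = 0.13). LEA genes had 2 of 20 lower at 11-12 days (9 when adjusted over the list alone; camera adjusted p = 7.7e-07, and adjusted p = 0.378 with an estimated correlation), with 1 of the 2 calls lost without PDAT A and both without CL37 A, CL37 B, PDAT B or PDAT C of that stage. Photosynthesis genes lay higher in PDAT as a list at that stage, with a median of 0.31 and none of 44 called in edgeR over all genes or over the list alone (14 at unadjusted p below 0.05, and 0 called in DESeq2; camera adjusted p = 9.63e-10, and adjusted p = 0.378 with an estimated correlation). Among the few genes that were higher over the mean of stages, AT5G35200, for an endocytosis adaptor, stood at 0.80 ± 0.11 (adjusted p = 0.000291). AT1G11070, for a cell wall glycoprotein, was higher by 0.60 ± 0.11 (adjusted p = 0.0048). FAD2 (0.01), FAD3 (0.10), ROD1 (0.02) and ATDGAT (-0.10) did not pass over the mean of stages, and ROD1 at 11-12 days was at 0.31 ± 0.15 (adjusted p = 0.48). Annotated terms among the lower genes at 11-12 days included response to cyclopentenone (11 of 45 genes, 1.25 expected, adjusted p = 6.81e-06) and response to chitin (8 of 40, adjusted p = 0.00142).

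**Figure D3:**
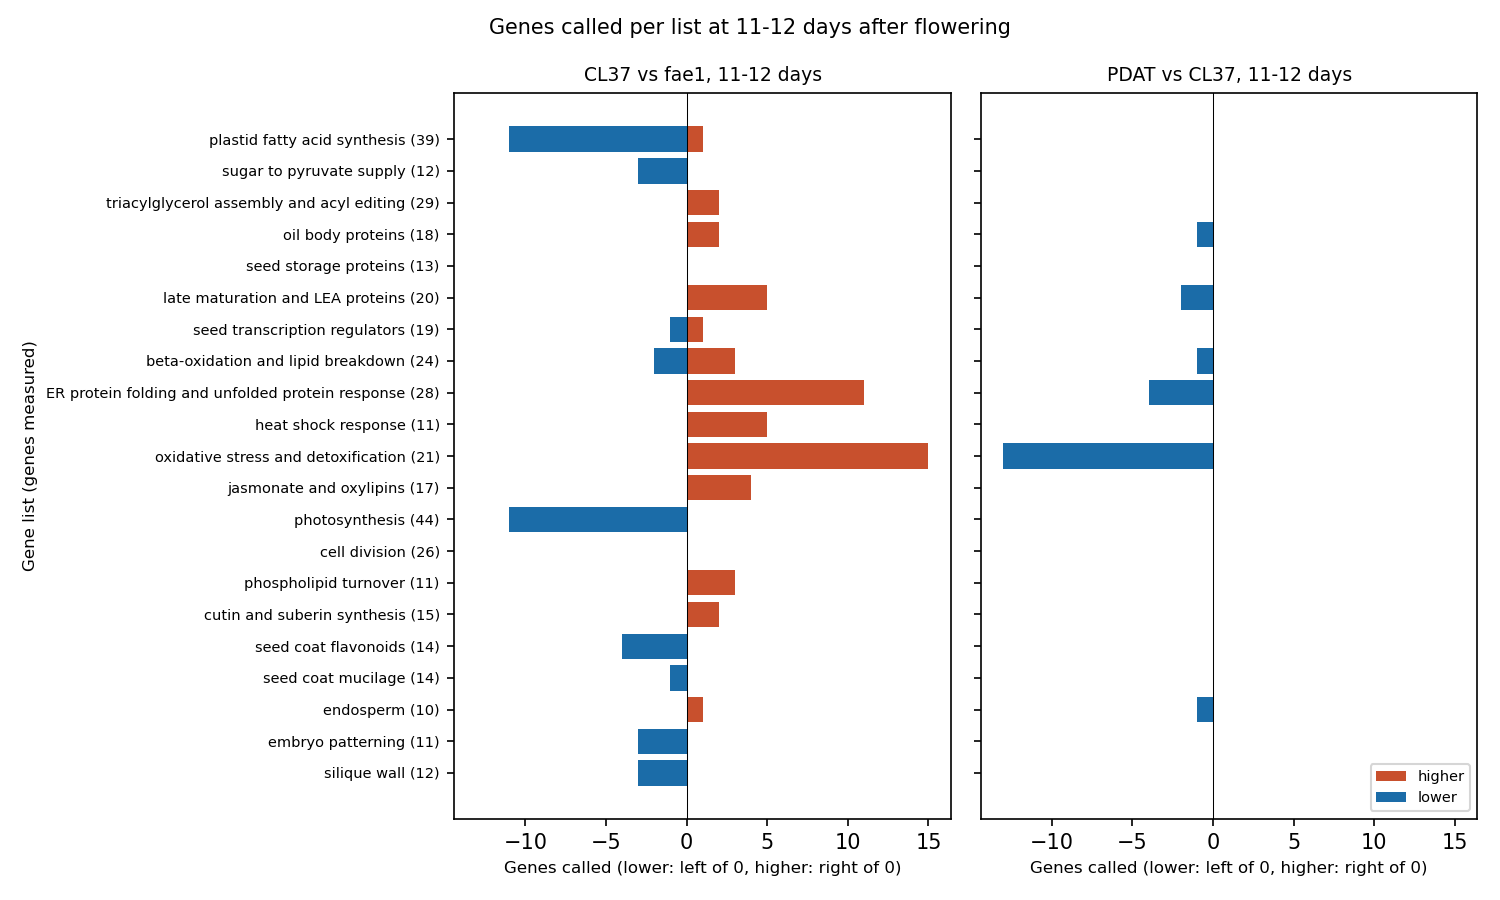
Number of genes called higher (bars to the right of 0) and lower (bars to the left) in each of the 21 gene lists at 11-12 days after flowering, for CL37 against fae1 and for PDAT against CL37. Detoxification had 15 higher in CL37 than in fae1 and 13 lower in PDAT than in CL37.

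Some heat shock, jasmonate and cutin genes stood higher in PDAT than in fae1, though none of these lists passed camera with an estimated correlation. ATMGL was low in PDAT, as it was in CL37. At 7-8 days, the comparison with fae1 gave many calls, among them lower translation genes, but few passed with the percent of non-unique alignments as a covariate, where the folds kept their direction and SEs grew. The fae1 A library of that stage takes part in all of them.

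PDAT against fae1 gave 901 genes higher and 731 lower at 7-8 days in edgeR, 12 and 5 at 9-10 days, and 932 and 317 at 11-12 days, with 696 and 411 over the mean of stages. The 1632 calls at 7-8 days fell to 31 (26 of them shared) with the percent of non-unique alignments as a covariate, and to 3 on the compared groups only. With the covariate all 1632 kept their direction, their median absolute log2 fold change went from 0.84 to 0.76 and their median SE from 0.21 to 0.29. The percent does not overlap between the 2 groups, so the lost calls do not show that the differences went away. At least 2-fold were 460 and 187 at 7-8 days and 514 and 62 at 11-12 days. Without the fae1 A libraries the counts were 2311 up and 1972 down, 6 and 5, 1739 and 1274, and 1001 and 737. Without the C libraries of fae1 and CL37 at 11-12 days they were 1196 at 7-8 days, 587 at 11-12 days and 680 over the mean of stages. At 7-8 days the total was 3909 without fae1 A, 865 without fae1 C, and 517, 585 and 644 without PDAT A, B and C. At 9-10 days it was 6 without fae1 A, 41 without fae1 C, and 8, 10 and 7 without PDAT A, B and C. At 11-12 days it was 577, 670 and 641 without fae1 A, B and C, 502 without PDAT A and 797 without PDAT C. For the mean of stages it was 2236 without fae1 A of 7-8 days, 712 without fae1 C of 11-12 days, 707 without PDAT B of 7-8 days and 737 without PDAT B of 11-12 days. DESeq2 gave 1132 up and 1157 down at 7-8 days, 52 up and 39 down at 9-10 days and 1039 up and 643 down at 11-12 days.

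ATMGL was lower in PDAT than in fae1 by 2.56 ± 0.17 over the mean of stages (adjusted p = 9.28e-10) and gave 74.2 ± 0.947 CPM at 11-12 days against 613.1 ± 53.1 in fae1. SCPL8 was lower by 1.76 ± 0.40 (adjusted p = 0.0105; 0.79 without fae1 A of 7-8 days). AT5G01380 stayed higher than in fae1 by 2.67 ± 0.30 (adjusted p = 8.88e-06) and AT5G13200 by 2.43 ± 0.36 (adjusted p = 0.000253). The cell wall gene XTR6 was higher by 2.29 ± 0.29 (adjusted p = 4.09e-05), the calcium sensor gene CML23 by 2.23 ± 0.27 (adjusted p = 1.8e-05) and PARG2 by 2.74 ± 0.31 (adjusted p = 7.52e-06). Of 15 cutin genes 3 were higher and 1 lower over the mean of stages (5 and 1 when adjusted over the list alone; camera adjusted p = 1.65e-05, and adjusted p = 0.228 with an estimated correlation). CYP86A2 was higher by 1.03 ± 0.08 (adjusted p = 4.91e-08), with 95.4 ± 7.25 CPM at 11-12 days against 34.4 ± 4.64 in fae1 and 71.7 ± 6.46 in CL37, and the acyl-CoA synthetase gene LACS2 by 0.47 ± 0.11 (adjusted p = 0.0154). Heat shock genes were higher in 3 of 11 cases (5 when adjusted over the list alone; camera adjusted p = 0.000457, and adjusted p = 0.228 with an estimated correlation). AT-HSFA3 was higher by 1.75 ± 0.35 (adjusted p = 0.00424), ATHSFA2 by 1.66 ± 0.38 (adjusted p = 0.0111) and the coactivator gene MBF1C by 1.42 ± 0.32 (adjusted p = 0.0107). Jasmonate genes were higher in 4 of 17 cases (5 when adjusted over the list alone; camera adjusted p = 0.00462, and adjusted p = 0.228 with an estimated correlation). RD22BP1 was higher by 1.23 ± 0.16 (adjusted p = 7.14e-05) and the lipoxygenase gene LOX3 by 0.89 ± 0.19 (adjusted p = 0.00771). The call of TIFY9 (0.49 ± 0.13, adjusted p = 0.0246) was lost without fae1 B or C of 11-12 days or PDAT C of 7-8 days (adjusted p of 0.0549, 0.0522 and 0.055). That of AOC3 (0.82 ± 0.23, adjusted p = 0.0376) was lost without fae1 B or C of 9-10 days, fae1 A, B or C of 11-12 days, PDAT A or B of 7-8 days, PDAT A or C of 9-10 days, or PDAT B or C of 11-12 days (adjusted p of 0.0587 to 0.0819). Of 28 ER stress genes 2 were higher (2 when adjusted over the list alone; camera adjusted p = 0.00462, and adjusted p = 0.571 with an estimated correlation). These were ATERDJ3A, higher by 0.80 ± 0.11 (adjusted p = 0.00012), and BZIP28, higher by 0.46 ± 0.10 (adjusted p = 0.00898). Of 21 detoxification genes 4 were higher (6 and 1 lower when adjusted over the list alone; camera adjusted p = 0.0594). Beta-oxidation genes included PEPCK, for an enzyme that turns oxaloacetate toward sugar (0.51 ± 0.09, adjusted p = 0.00172), and LACS7 (0.66 ± 0.15, adjusted p = 0.0108). Of 14 flavonoid genes 3 were lower (6 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00462, and adjusted p = 0.452 with an estimated correlation). TT5 was lower by 0.62 ± 0.11 (adjusted p = 0.0016). With 1 library left out, 2 jasmonate genes were called without fae1 B or C of 11-12 days. Of the detoxification genes 2 were called without fae1 A of 9-10 days, fae1 B or C of 11-12 days, PDAT B of 7-8 days or PDAT A of 9-10 days. Leaving out fae1 A of 7-8 days gave 6 heat shock and 5 ER stress genes. With the percent of non-unique alignments as a covariate 1 jasmonate gene and 2 heat shock genes were called. The calls of SCPL8 (-1.20 ± 0.49, adjusted p = 0.188), LACS2 (0.46 ± 0.14, adjusted p = 0.0783), MBF1C (1.17 ± 0.38, adjusted p = 0.0937), LOX3 (0.69 ± 0.23, adjusted p = 0.0978), TIFY9 (0.48 ± 0.16, adjusted p = 0.0908) and AOC3 (0.59 ± 0.26, adjusted p = 0.219) ended there, with larger SEs than before.

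At 7-8 days the lower genes in PDAT held 95 of 365 translation genes (14.8 expected, adjusted p = 1.93e-50), whose median was -0.47 against -0.29 for genes of the same length and abundance. The term test takes genes as independent, so its p can be too small. That excess rests on 731 lower genes, a count that was 16 with the percent of non-unique alignments as a covariate and 1 on the compared groups only. LEA genes were lower in 3 of 20 cases (4 when adjusted over the list alone; camera adjusted p = 0.00368, and adjusted p = 0.713 with an estimated correlation), and the fae1 A library, whose LEA transcripts lay with those of 9-10 days, is in that contrast. LEA counts ran from 1 (without fae1 A, PDAT A or PDAT B) to 11 (without fae1 B). ROD1 was lower by 0.54 ± 0.15 at 7-8 days (adjusted p = 0.0328), lost without fae1 B or C (adjusted p of 0.0643 and 0.0818) or without PDAT A, B or C (0.13, 0.0618 and 0.0725), and with the percent of non-unique alignments as a covariate (-0.57 ± 0.21, adjusted p = 0.187). At 11-12 days ATGSTU22 was higher in PDAT than in fae1 by 5.17 ± 0.67 (adjusted p = 2.9e-05) and PARG2 by 5.36 ± 0.43 (adjusted p = 4.07e-08), and annotated terms among the higher genes included response to chitin (13 of 40, adjusted p = 5.75e-06). At 9-10 days the remorin gene AT2G02170 was among the 12 genes higher in PDAT, by 1.38 ± 0.20 (adjusted p = 0.00171).

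The line differences were compared with the course of development and with each other. At 9-10 days the CL37 minus fae1 difference followed the fae1 change with age (slope 0.28, r = 0.60). These are across genes, which are not independent replicates. The exact permutation p over the 20 splits of the 6 libraries was 0.1, the smallest that 3 against 3 libraries allow (two-sided), and the slope was 0.17 without fae1 A of 9-10 days and 0.13 without both fae1 A libraries. Against the PDAT change it was -0.16 at 7-8 days (-0.0031 without the fae1 A libraries), 0.23 at 9-10 days and 0.18 at 11-12 days. The PDAT minus CL37 slope was -0.05 (exact permutation p = 0.3). The CL37 effect at a stage and the PDAT effect at another stage, which share no library, had a mean covariance of -0.027 across genes over 6 pairs, negative in 4, against a mean of -0.0000550 in 20 simulations without effects. Its SD over the 6 pairs was 0.048, and the simulations drew genes independently. For genes with an average log2 CPM of at least 4 the mean covariance was -0.0106, negative in 3 of 6. Within a stage, where the CL37 libraries are shared, it was -0.115 against -0.0629 simulated. By stage it was 0.0233 at 7-8 days (-0.0560 simulated), -0.109 at 9-10 days (-0.0758) and -0.259 at 11-12 days (-0.0568). The mean correlation within a stage was weaker than simulated (-0.374 against -0.532). The 133 genes higher in CL37 than in fae1 at 9-10 days had, at 11-12 days, a median of 2.62 for CL37 minus fae1, -0.82 for PDAT minus CL37 and 1.73 for PDAT minus fae1, and 80.5% of them lay lower in PDAT than in CL37 against 46.5% of all genes. Called without the fae1 A libraries, such genes numbered 92 with a median of -0.70, and 64.1% lay lower. At 11-12 days 475 of the 482 genes lower in PDAT than in CL37 were among the 1990 higher in CL37 than in fae1, where independent lists would share 50.8, though both comparisons use the same CL37 libraries. Of the 932 genes higher in PDAT than in fae1 at that stage, 805 were among the 1990 (98.1 if independent), and of the 317 lower, 245 were among those lower in CL37 (16.0 if independent), with the same fae1 libraries in both comparisons.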

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

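Chosen after the results were seen were the tests with the developmental score or the percent of non-unique alignments as a covariate, the upper-quartile count, the share of genes back toward fae1, the 3 tests on the fae1 A libraries, and the splits of libraries at single stages.

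From 7-8 to 11-12 days the edgeR interaction tests called a change of the line difference for 133 genes between PDAT and CL37, 1444 between PDAT and fae1 and 1239 between CL37 and fae1. Chance was not excluded for CL37 and fae1 (11 of 100 splits as large) or for PDAT and fae1 (3 of 100, highest other 1713). The percent of alignments that were not unique, used only as a covariate, was 8.06 points higher in PDAT than in fae1 at 7-8 days. It was 16.6% to 19.4% in PDAT and 6.28% to 11.4% in fae1 (3 libraries each). In the authors' pooled FPKM column of CL37 at 11-12 days, 29.89% of the fitted weight fell on fae1 libraries of the same stage.

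The first pattern is the set of 2942 genes that differed between CL37 and fae1 at 11-12 days, where the CL37 libraries also had higher developmental scores. A few abundant genes taking most counts stay open for the excess of higher genes. Upper-quartile scaling called 1810 up and 1491 down. It moved the median of all genes by -0.057, too little to test most calls, and 2761 of the 2942 stayed. A more advanced age of CL37 seeds is argued against as the whole cause, since 1862 stayed called, all in the same direction, with the score as a covariate. That fit called 2179 up and 2160 down against 1990 and 952 without it, so the excess of higher genes did not stay. Of the called genes 77.9% differed in the direction of their own change in PDAT. The bound set in advance was 75%, and all genes had 62.5%. The design names an effect of the hydroxylase, but each line is 1 line, so it was not separated from other line differences.

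The second pattern is the set of genes lower in PDAT than in CL37 at 11-12 days. Less advanced PDAT seeds stay open as a cause. With the score as a covariate 422 of the 500 stayed called, but that adjustment rests on the same differences within groups. The score was also built from PDAT libraries. Non-unique alignments are argued against as the whole cause, since 334 of the 500 stayed called with their percent as a covariate. Chance values of the CL37 libraries that both comparisons share stay open. Of the genes that rose in CL37 at 9-10 days, 80.5% lay lower in PDAT at 11-12 days, in other libraries, against 46.5% of all genes. Without the fae1 A libraries the share was 64.1%, under the set 20 points above all genes. Its spread is unknown, as genes vary together. An effect of the castor acyltransferase also stays open as a hypothesis, with PDAT being 1 line.

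The third pattern is the pair of fae1 A libraries of 7-8 and 9-10 days, which stood apart from their groups. Libraries of another line are argued against, since the lower of their ATMGL levels was 327 CPM against at most 130 CPM in CL37 and PDAT. An exchange of their stage labels stays open, since the values point both ways. The score of the A library of 9-10 days lay 1.02 above the highest other library of 7-8 days, whose scores spanned 0.54. Yet its 3 nearest libraries by rank correlation were all of 7-8 days, with a mean of 0.969 to the CL37 group of 7-8 days against 0.962 to its own group. Older seeds in the 7-8 day library, or a wrong stage label of it alone, remain candidates. Its score of -0.62 lay within those of the fae1 libraries of 9-10 days. No biological explanation was tested.

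Other splits of the same libraries were counted for each comparison. At 3 against 3 libraries the 10 splits are too few for a share under 0.05. There, CL37 against fae1 had 5 genes at 7-8 days, where 2 splits gave as many and the highest other gave 1002. This points to a structure of these samples, with the fae1 A library apart. For the other 8 single-stage comparisons 1 split, the real one, gave as many. The real counts with the highest other split in brackets were 140 (0) at 9-10 and 2942 (0) at 11-12 days for CL37 against fae1, 2 (0), 4 (1) and 500 (2) for PDAT against CL37, and 1632 (1214), 17 (0) and 1249 (0) for PDAT against fae1. Development gave 9540 (4774) in fae1, 10979 (0) in CL37 and 10181 (0) in PDAT, each with 1 split as large.

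Over the mean of stages and for interactions 100 splits were drawn. With the real one counted, 2 splits called as many genes for CL37 against fae1 over the mean of stages (1338 genes, highest other 3097). For PDAT against fae1 3 splits did so over the mean (1107, highest other 2299) and 3 in the interaction (1444, highest other 1713). These shares were under 0.05, yet other splits called more genes than the real one, so chance was not excluded. For PDAT against CL37 only the real split called as many, which argues against chance. The counts were 154 over the mean (highest other 131) and 133 in the interaction (highest other 100). Chance was not excluded either for the interaction of CL37 and fae1 (1239 genes, 11 splits as large, highest other 1524). Splits that called more than the real one point to a structure of the samples beyond the groups.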

How the results depend on the processing

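Chosen after the data were seen were the fits without the fae1 A libraries of 7-8 and 9-10 days, without the fae1 and CL37 C libraries of 11-12 days, with the developmental score or the percent of non-unique alignments as a covariate, and the axis from the line that is not in the difference, as well as the counts of called list members with 1 library left out. Counts of called genes below are compared with those of the report, and a count within 1.5-fold is taken as kept. RLE and upper-quartile scaling kept every such count. Upper-quartile scaling moved the median of all genes by -0.15 for CL37 development, the only shift above 0.1.

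Without a filter on low counts the count was 3 for CL37 against fae1, 0 for PDAT against CL37 (2263 at unadjusted p below 0.05) and 1081 for PDAT against fae1 at 7-8 days, and 957 for the interaction of PDAT and fae1, where more genes were tested. With the replicate block it was 3 for CL37 against fae1 and 6 for PDAT against CL37 at 7-8 days, and no other count moved beyond 1.5-fold. DESeq2 gave 114 and 268 for CL37 against fae1 at 7-8 and 9-10 days, 85, 26 and 301 for PDAT against CL37 at 7-8 days, at 9-10 days and over the mean of stages, 91 for PDAT against fae1 at 9-10 days, and 268 and 2303 for the interactions of PDAT with CL37 and with fae1. The cause was not tested.

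Fitted on the compared groups only, with fewer libraries, CL37 against fae1 gave 0 at 7-8 days (474 at unadjusted p below 0.05) and 52 at 9-10 days, and PDAT against CL37 gave 0 at 9-10 days (1256 at unadjusted p below 0.05). On these groups PDAT against fae1 gave 3, 1, 1976 and 737 at the 3 stages and over their mean, fae1 development gave 3486, and the interactions of CL37 and of PDAT with fae1 gave 587 and 242.

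Without the fae1 A libraries the counts were 8 (7-8 days) and 4473 (11-12 days) for CL37 against fae1, 37, 765 and 290 for PDAT against CL37 (7-8 days, 11-12 days and mean), and 4283, 11, 3013 and 1738 for PDAT against fae1 (3 stages and mean). The interactions were 3270 (CL37 and fae1), 381 (PDAT and CL37) and 5320 (PDAT and fae1). Without the C libraries of fae1 and CL37 at 11-12 days the counts were 3 and 1940 for CL37 against fae1 (7-8 and 11-12 days), 0 for PDAT against CL37 at 7-8 days (1981 at unadjusted p below 0.05), 587 and 680 for PDAT against fae1 (11-12 days and mean), and 675 for the interaction of PDAT and fae1.

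With the developmental score as a covariate the counts were 2, 79 and 2431 for CL37 against fae1 (7-8 days, 9-10 days and mean), 16 for PDAT against CL37 at 7-8 days, 31, 3896 and 2345 for PDAT against fae1 (9-10 days, 11-12 days and mean) and 3059 for its interaction. Development gave 0 genes in fae1 (775 at unadjusted p below 0.05), 54 in CL37 and 30 in PDAT, which follows from the score being built from the change with age. With the percent of non-unique alignments as a covariate the counts were 2 for CL37 against fae1 at 7-8 days, 1, 14 and 59 for PDAT against CL37 (7-8 days, 9-10 days and mean), 31, 803 and 663 for PDAT against fae1 (7-8 days, 11-12 days and mean), and 6115 and 5356 for development in fae1 and PDAT. The cause was not tested.

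Leaving out 1 library gave 2 to 161, 42 to 175, 1659 to 3281 and 1013 to 2088 genes for CL37 against fae1 at 7-8, 9-10 and 11-12 days and over their mean. It gave 0 to 3, 0 to 39, 278 to 514 and 83 to 204 for PDAT against CL37, and 517 to 3909, 6 to 41, 502 to 1454 and 707 to 2236 for PDAT against fae1. Development ranged from 6207 to 11619 in fae1, 9791 to 10504 in CL37 and 8812 to 10254 in PDAT. The interactions ranged from 692 to 3045 (CL37 and fae1), 68 to 175 (PDAT and CL37) and 354 to 5025 (PDAT and fae1).

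Of 84 list tests (21 lists in 4 contrasts), camera called 35 at the preset correlation and 2 with an estimated correlation. The slope of CL37 minus fae1 on the fae1 change was 0.281, and 0.1312 without the fae1 A libraries. On the PDAT change it was -0.1634 at 7-8 days (-0.0031 without the A libraries), 0.1482 at 9-10 days without the A libraries, and 0.1816 at 11-12 days with and without them. The slope of PDAT minus CL37, -0.054 at 9-10 days, was 0.0087 and 0.0098 at 7-8 days. Leaving out 1 library gave slopes of 0.166 to 0.358 and of -0.0866 to -0.0357. Recovery in PDAT had a median of -0.82, -1.26 for genes called at adjusted p below 0.01 and -0.70 without the fae1 A libraries. The share that lay lower was 80.5%, 88.1% and 64.1% in these fits, against 46.5% of all genes. The mean covariance of CL37 and PDAT effects between stages was -0.027 (negative in 4 of 6 pairs), -0.0106 (3 of 6) for genes with an average log2 CPM of at least 4 and -0.0307 (4 of 6) without the fae1 A libraries.

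Of 139 values of named genes that were called, 138 stayed called under RLE, 137 under upper-quartile scaling, 129 without the filter, 137 with the replicate block, 139 in DESeq2, 109 on the compared groups only, 134 without the fae1 A libraries, 127 without the C libraries, 88 with the score and 112 with the percent of non-unique alignments. Of these, 30 were lost without some library. The 139 values are of genes that the text describes, and it leaves out most genes whose call was lost without 1 library. These counts therefore do not hold for all genes chosen by the rule. PDAT2 (AT3G44830), not called for PDAT against fae1 at 7-8 days, was called at 1.06 without fae1 A of 7-8 days, alone or with fae1 A of 9-10 days, and ranged from -0.54 to 1.06 with 1 library left out. With the score, SYP111 was at 0.40 for CL37 against fae1 over the mean of stages. Development with the score had the other sign in fae1 for FAD3 (-0.74), PDAT2 (-0.14), FAE1 (-0.42), FAD2 (-0.14), DGAT1 (-0.25), ICL (-1.07), LACS7 (-0.074), PCNA1 (0.10), ATS1 (-1.12), OLE3 (-0.82), SESA1 (-1.89), CRU3 (-1.32), CRU1 (-1.14), LEC2 (0.35) and LEC1 (0.93), none of them called. It had the other sign in CL37 for FAD3 (-2.50), PDAT2 (-1.75), FAD2 (-0.29), FAE1 (-1.94) and DGAT1 (-0.52), and in PDAT for FAD3 (-1.69), FAE1 (-1.30), PDAT2 (-1.96) and DGAT1 (-0.71). None of these was called in edgeR (adjusted p of 0.237 to 0.895). These signs decide nothing about development, since the score was built from the change with age. The interaction of CL37 and fae1 gave FAD3 at -1.75 with the score.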

Other observations

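The ATMGL region test and both FPKM column tests were planned before their results, but after the patterns that led to them, were seen.

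ATMGL stood lower in CL37 and PDAT than in fae1 at every stage. A candidate explanation was a chromosome segment around it that differs between the lines and changes several neighbours. Of 96 tested genes within 250 kb, 5 were called between CL37 and fae1 over the mean of stages, 5.21% against 7.08% of all tested genes, which argues against a segment with many changed genes. A change at ATMGL alone was not tested.

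The authors' pooled FPKM values of fae1 and CL37 at 11-12 days lay nearer to each other than the counts did. ATMGL, for example, was 275.87 FPKM in fae1 and 163.18 in CL37, and 45.91 in PDAT. A candidate explanation is that each pool held a library of the other line: the lower of the 2 fitted weights on libraries of other lines at that stage was 26.77%, above the 20% that had been set for it. The fae1 column fitted as fae1 A (36.23%), fae1 B (28.52%) and CL37 C (25%), and the CL37 column as CL37 A (25.18%), CL37 B (36.08%) and fae1 C (28.7%), as if the C libraries had been exchanged in the pools. A mix of lines in every column is argued against by the CL37 column of 9-10 days, whose weight on other lines at its stage was 2.46%, though the CL37 column of 7-8 days had 16.38%, above the 10% bound set in advance for both. In the counts, the ATMGL levels of both C libraries went with their labels (606 CPM in fae1 C and 130 CPM in CL37 C).

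Gene length was related to the line differences. Across 18766 genes, which are not independent replicates, Spearman's rho between transcript length and the log2 difference of PDAT and fae1 was 0.30, 0.424 and -0.401 at 7-8, 9-10 and 11-12 days. Between CL37 and fae1 it was 0.223, 0.246 and -0.279.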
